A study of Rattus norvegicus with 3 samples.

How the data were processed

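Total RNA from 3 cultures of fetal Wistar rat cardiomyocytes was extracted with a Qiagen RNeasy mini kit, labelled with biotin by the Affymetrix 3' IVT Express procedure and hybridised to 1 array per culture, per the labels' protocols. The groups were fresh medium (control), skeletal myoblast-conditioned medium and cardiac fibroblast-conditioned medium, with 1 array each. RMA, which subtracts background, equalises the distributions of the arrays and summarises the probes of each probe set by median polish, is named in the submitters' processing notes. Its software, version and settings are not given in the sources used here.

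The deposited values are on a log2 scale and are centred on each probe set's own median over the 3 arrays, as the values themselves show. The table held 31099 probe sets. In 17117 of them 2 arrays had a value, always 1 positive and 1 negative, 8002 had 1 value, 5980 had none and 0 had 3, and no value was exactly 0. Blank cells were therefore read as 0, the median array. Probe sets with fewer than 2 values were read as ties. Median polish of 5000 simulated probe sets with 11 probes on 3 arrays gave such ties. Where the SD between arrays was 0.5 of the probe SD, 47.0% of probe sets had 2 values, 33.6% had 1 and 19.4% had none, against 55.0%, 25.7% and 19.2% observed. That ratio was the closest to the data of those tried. Ratios from 0 to 2 gave from 16.7% to 91.9% of probe sets with 2 values. The log base is taken from the use of RMA, and the range from -7.82 to 6.73 is too wide for log10. Centring removes the absolute level, so how bright a gene was is unknown, and so is signal over background. With blanks as 0, the median of each array was 0.

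The platform annotation, which is dated, paired 20832 probe sets with 1 gene and 436 with several, and 9831 were unnamed here. Symbols were updated through Entrez IDs with the RefSeq gene table of assembly GRCr8, which matched 20764 of the named probe sets. No coordinates are given. Probe sets with several genes were not used to name a gene. A gene's value was the mean of its probe sets with 1 symbol, which gave 14217 genes, 4525 of them with 2 or more probe sets and 1627 at 0 on all arrays.

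The design fixed before the data were examined used the brightest probe set of a gene, a floor on dim genes and random lists matched on mean level. None of these can be computed from centred values. The mean of the probe sets and no floor, both planned as alternatives, took their place, and random lists were matched on the number of probe sets (1, 2, or 3 and more). Differences of log2 values were taken for each pair of conditions, and genes with an absolute difference of at least 1 were counted. With 1 array per condition no test of the conditions exists. For each of 37 gene lists of that design, with at least 5 measured members, the median difference was placed among those of 10000 random lists of the same size. A list was said to stand apart outside the central 95%, below percentile 2.5 or above 97.5. This describes these arrays and is not a test. Random lists could draw the genes at 0 on all arrays, and some lists with medians near 0 stood apart. With only genes that had a nonzero value, 67 of 73 list calls over the 3 comparisons were kept. Of 994 list entries, 107 had no probe set with that symbol alone and were not analysed here, and the list medians cover the others. The ribosomal protein list kept 22 of 41 genes, the p53 target list 17 of 24, the erythroid list 13 of 19 and the reference list 12 of 17.

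The genes named are the 12 largest positive and 12 largest negative differences of each comparison, leaving out symbols that start with LOC, RGD, MGC or AABR or end in _predicted; every measured member of the EGFR and c-Met family list; and, for a list described, up to 4 members with the largest difference in the direction of its median and up to 2 the other way. Not every such gene is printed. The comparison of both media names genes from the tables of the largest differences and from the list examples. Added control transcripts were grouped into 18 probe sets for hybridisation controls and 24 for poly-A controls. The correlation between the media was set beside 3 simulated unchanged arrays with an SD of 0.235 per array, from the spread of myoblast medium minus control split equally between both arrays.

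The counting and list steps were tested on simulated data for myoblast medium against control, over 14217 genes. All 200 genes changed by 2 on the log2 scale passed 2-fold in the right direction, and 30 unchanged genes passed it. A list shifted by 0.50 had a median of 0.44 at percentile 100 of 2000 random lists, and 2 of 36 other lists stood apart. Also tried, as chosen beforehand, were the median of a gene's probe sets, leaving out cross-hybridising probe sets, centring each array on its median, thresholds of 1.5-fold and 3-fold, and random lists that were not matched. Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.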

Results

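Gene expression was measured in cardiomyocytes isolated from fetal Wistar rats, an outbred laboratory strain, that had been plated for 48 hours and then kept for 24 hours in one of 3 media. Fresh medium served as the control. The other cultures received medium conditioned by skeletal myoblasts, the proliferating precursor cells of skeletal muscle, or medium conditioned by cardiac fibroblasts, the main matrix-producing cells of the heart. Conditioned medium carries what the donor cells secreted and lacks what they consumed. Each condition was hybridised to 1 Affymetrix 3' expression array, so none of the 3 differences has a replicate check, a standard error or a p-value, and all values below describe these arrays. The number of arrays limits the precision. Values are log2 differences between arrays for 14217 genes, where 1 is 2-fold. The only measured yardstick of technical error was 42 probe sets for control transcripts that are meant to be added to every sample in equal amounts. Whether the amounts were equal here is not known. Their largest difference was 0.66 between myoblast medium and control, 0.68 in size between fibroblast medium and control, and 1.02 between the conditioned media.

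**Figure D1:**
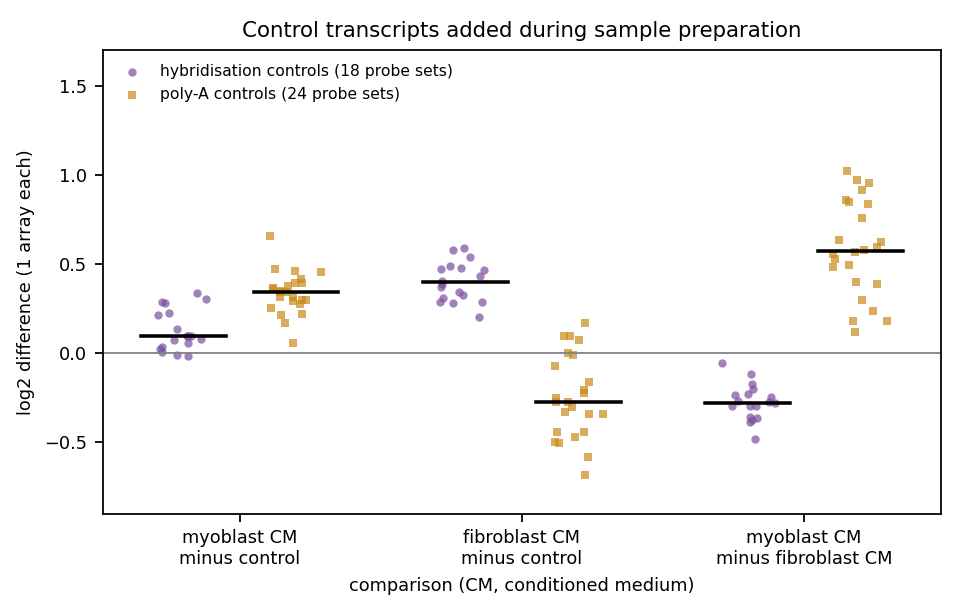
Log2 differences (vertical axis) of 18 hybridisation control and 24 poly-A control probe sets in the 3 comparisons (horizontal axis), 1 array per condition. Points are probe sets and black bars are medians; the poly-A controls had a median of 0.34 for myoblast medium minus control and -0.27 for fibroblast medium minus control.

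The first comparison set myoblast-conditioned medium against fresh medium, and addresses which transcripts differ in cardiomyocytes exposed to what myoblasts release, in a study concerned with paracrine protection from oxidative stress through the receptors c-Met and EGFR. Genes of the ATF4 and amino acid response were higher as a group. Of 37 measured members, 27 were at least 2-fold higher and none was 2-fold lower, with a median log2 difference of 1.31. The largest were Trib3, a pseudokinase gene, at 3.82 (14.1-fold), Ddit3, which encodes the stress transcription factor CHOP, at 3.09 (8.51-fold), the cystine transporter Slc7a11 at 3.00, and Chac1, which encodes a glutathione-degrading enzyme, at 2.34. All 37 members had a difference above 0. The endoplasmic reticulum chaperone genes had a median of 0.76, and 10 of 24 were at least 2-fold higher. Among them were Creld2 at 2.44, Sdf2l1 at 2.36, Herpud1, a component of protein degradation at the endoplasmic reticulum, at 2.03, and the co-chaperone Dnajc3 at 1.82. No random list among 10000 matched in size and in number of probe sets had a median as high as either of these lists.

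Among genes with probe sets of a single symbol, the largest difference was that of Cth, which encodes the cysteine-producing enzyme cystathionine gamma-lyase, at 4.15 (17.8-fold higher in myoblast medium). Abcb1a, a drug efflux pump, was higher by 3.16, Cnn1, a smooth muscle calponin, by 3.02, Angptl8 by 2.63, the arginine transporter Slc7a3 by 2.52, Akr1c15 by 2.52, Steap1 by 2.42 and Slc25a33 by 2.36. The lowest were Txnip and Arrdc4, related arrestin-family genes that glucose is known to induce, at -3.68 (12.8-fold) and -3.64 (12.5-fold). Pla2g2a, a secreted phospholipase, followed at -3.31, then Sox7, an endothelial transcription factor, at -3.01, Sned1 at -2.84, Spon2 at -2.39, Islr at -2.13 and the collagen gene Col6a6 at -1.97. Prnd (-1.93), the interferon regulatory factor Irf7 (-1.92), Afap1l2 (-1.90) and the vascular connexin gene Gja4 (-1.89) completed the 12 lowest. Counts were 192 genes at least 2-fold higher and 120 at least 2-fold lower in myoblast medium. Of the 62 such genes with more than 1 probe set, 0 had a probe set of opposite sign.

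Redox genes were not uniform in this comparison. Of 21 targets of Nrf2, the transcription factor that controls antioxidant defence, 5 were at least 2-fold higher and none 2-fold lower, with a median of 0.29. They included Slc7a11, which the ATF4 list also holds, the quinone reductase Nqo1 at 2.15, the sulfiredoxin Srxn1 at 1.15 and Gclc, the catalytic subunit of glutathione synthesis, at 1.13, while Gsta4 was at -0.53 and Cbr1 at -0.36. The 23 antioxidant enzyme genes had a median of 0.00 inside the central 95% of random lists. The metallothionein genes Mt2A, at 1.75, and Mt1 (2.83-fold) were higher, against Glrx at -0.74 and Selenop at -0.66. The 34 HIF targets and glycolysis genes had a median of 0.43 and 5 were at least 2-fold higher, including Bnip3 at 1.52, Stc2 at 1.44, Ankrd37 at 1.29 and the hexokinase gene Hk2 at 1.24. Aldoc (-0.29) and Ndrg1 (-0.28) went the other way. Genes of fatty acid synthesis had a median of 0.29, with Scd at 1.73 and Srebf1 at 1.52, and genes of cholesterol synthesis a median of 0.27, with Fdps at 1.25 and Cyp51 at 1.19.

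Receptors and ligands of the EGFR and c-Met families did not stand apart under myoblast medium. None of 16 measured members reached 2-fold and the median was 0.00, with 5 members at exactly 0. Met, the hepatocyte growth factor receptor, was at -0.01. Hgf and Mst1, each with 1 probe set, had no value on any array, so their 0.00 comes from blanks read as 0. Egfr was at -0.40, Erbb2 at -0.52, Erbb3 at -0.15 and Erbb4 at 0.06. Among the ligands, Tgfa was at 0.63, Egf at 0.36, Hbegf at 0.23, Areg at 0.16, Btc at -0.10, and Ereg, Mst1, Hgfac and Nrg2 at 0.00. Nrg1 had a mean of 0.14 over 8 probe sets that disagreed in sign, from -0.19 to 0.60. The 28 MAPK feedback and immediate-early genes also had a median of 0.00, but 1 was at least 2-fold higher (Myc) and 1 at least 2-fold lower (Errfi1). The 30 genes that promote or restrain apoptosis, Bnip3 among them, had a median of 0.00, with Bcl2l11 at -0.62.

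Markers of other cell types differed as well. In myoblast medium, 4 of 18 endothelial marker genes were at least 2-fold lower and none higher (median -0.49), with Emcn at -1.38, Pecam1 at -1.23, Esam at -1.10 and Tie1 at -1.03. Macrophage and leukocyte markers had a median of -0.41, with Mrc1 at -0.94 and Lyz2 at -0.88, although Fcgr2b was higher by 1.13. Skeletal myoblast and myofibre markers did not differ beyond the random lists, with 0 of 23 past 2-fold and a median of -0.03. Cardiomyocyte contractile and marker genes had a median of -0.16. Among its 33 members the myoglobin gene Mb was lowest at -1.42, and 3 were at least 2-fold higher, including the slow myosin gene Myh7 at 1.43 and the Z-disc gene Csrp3 at 1.29. Of 17 hypertrophy and stretch markers, 5 were at least 2-fold higher (median 0.36), with Nppb, the gene of B-type natriuretic peptide, at 2.02, Acta1 at 1.73 and Gdf15 3.25-fold higher. Myofibroblast and TGF-beta target genes had a median of 0.24, with Cnn1 joined by Acta2 at 1.98 and Tagln at 1.33. Interferon-response genes were lower, with 5 of 34 past 2-fold and a median of -0.20, including Mx2 at -1.80, Rtp4 at -1.40 and Isg15 at -1.33. In all, 24 of the 37 lists lay outside the central 95% of random lists. Lists of randomly drawn genes would give 1.85, but genes of a list may vary together, so the excess is no measure of chance. The ATF4 and chaperone lists had medians beyond the largest difference of the added control transcripts under every setting tried. The endothelial median also lay beyond it under 3 settings chosen after the data were seen, at -0.66 with only genes that had a nonzero value, -0.71 with the probe set with the widest range and -0.72 with only probe sets that had values on 2 arrays. The interferon-response median did under the last of these, at -0.67.

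**Figure D2:**
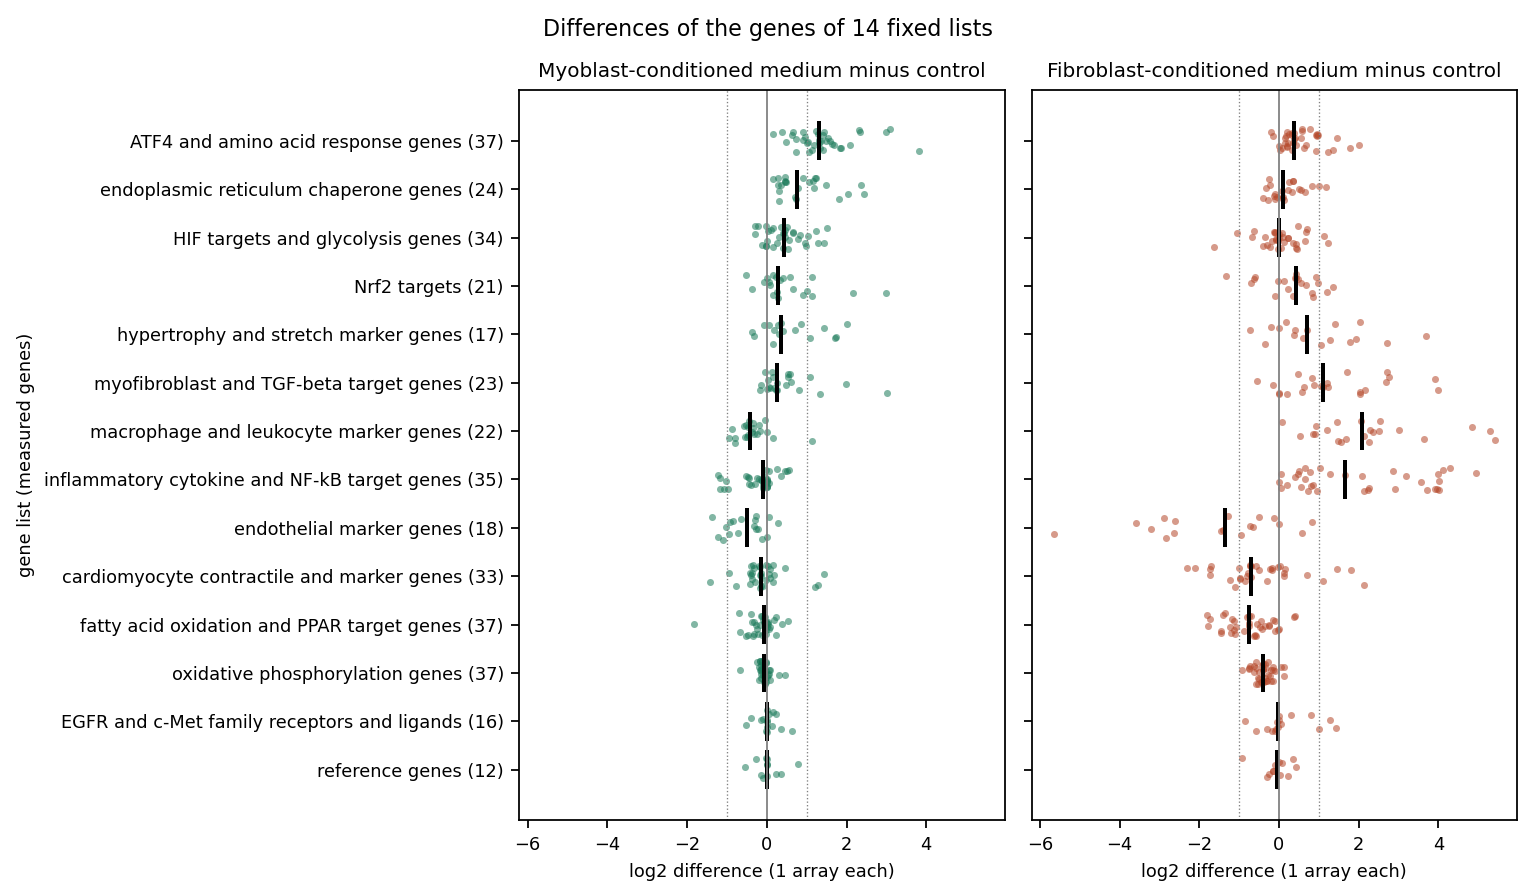
Log2 differences (horizontal axis) of the measured genes of 14 fixed lists (vertical axis) for myoblast-conditioned medium minus control (left) and fibroblast-conditioned medium minus control (right). Each point is a gene, black bars are list medians, dotted lines mark 2-fold, and 1 array stands for each condition; the highest list median is 1.31 on the left (ATF4) and 2.09 on the right (macrophage).

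The second comparison set fibroblast-conditioned medium against fresh medium. Macrophage and inflammatory genes were higher. Of 22 macrophage and leukocyte markers, 17 were at least 2-fold higher and none was lower than in control, with a median of 2.09. They were led by Adgre1, which encodes a macrophage surface receptor, at 5.41 (42.6-fold), the Fc receptor gene Fcgr2b at 5.29, the lysozyme gene Lyz2 at 4.85 and the lipopolysaccharide co-receptor Cd14 at 3.65. Of 35 inflammatory cytokine and NF-kB target genes, 20 were at least 2-fold higher, with a median of 1.65. Il1b was higher by 4.94 (30.7-fold), Il6 by 4.29 (19.6-fold), the chemokine gene Ccl7 by 4.11 and Ptgs2, which encodes cyclooxygenase-2, by 4.02. Acute phase and STAT3 target genes had a median of 0.57, with Ch25h, a cholesterol hydroxylase, at 4.82, Spp1 at 2.17 and Reg3b 3.99-fold higher. Interferon-response genes went the other way, with a median of -0.20 and 8 of 34 at least 2-fold lower, among them Rtp4 at -1.67, Irf7 at -1.56 and Usp18 at -1.53, although the immunoproteasome genes Psmb8 (1.09) and Psmb9 (1.03) were higher.

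Among genes with probe sets of a single symbol, the largest difference was that of Grem1, a secreted antagonist of bone morphogenetic proteins, at 7.48 (179-fold higher in fibroblast medium). Ccn3, a matricellular protein gene, was higher by 4.63, the chemokine gene Ccl9 by 4.48, Serpinb2, a plasminogen activator inhibitor, by 4.35, Scg2 by 4.31 and Rnd1 by 4.30. Myofibroblast and TGF-beta target genes were higher as a group, with 13 of 23 at least 2-fold higher, none lower and a median of 1.09. Ltbp2 was 16.0-fold higher, Col8a1 at 3.92, Tagln at 2.75 and Ccn2, the gene of connective tissue growth factor, at 2.70, against Cthrc1 at -0.55. Fibroblast and collagen matrix genes had a median of only 0.20, with Mfap5 at 3.88, Lox at 2.89 and Thy1 at 1.69 higher and Fbln1 (-2.07) and Pdgfra (-1.48) lower. Of 17 hypertrophy and stretch markers, 8 were at least 2-fold higher (median 0.72), led by Nppb at 3.70 and Ccn2, while Acta1 was at -0.72. Secreted growth and angiogenic factors included Inhba at 3.25, Igfbp2 at 2.94 and Tgfb2 at 2.30, with Angpt2 at -2.72 and Mdk at -2.01, around a median of 0.22.

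Endothelial, cardiomyocyte and mitochondrial genes were lower under fibroblast medium. Of 18 endothelial markers, 10 were at least 2-fold lower and none was 2-fold higher, with a median of -1.35. Emcn was lowest of all named genes at -5.65 (50.3-fold), and the tight junction gene Cldn5 was at -3.58, Sox18 at -3.22 and Tie1 at -2.90, against Eng at 0.83. Flt1 had a mean of 0.58 over 3 probe sets that disagreed in sign, from -0.19 to 1.20. The other genes with the lowest values were Sparcl1 (-5.34), Col6a6 (-5.22), Sox7 (-4.94), Dhrs7c, a dehydrogenase gene of striated muscle (-4.56), Prnd (-4.48), the haemoglobin gene Hbb (-4.32), Gstt3 (-3.70), the imprinted gene Mest (-3.64), Capn6 (-3.60) and the lymphatic marker Lyve1 (-3.59). Of 37 genes of fatty acid oxidation and PPAR targets, 14 were at least 2-fold lower and 0 higher, with a median of -0.76. Plin5 was at -1.80, Decr1 at -1.79, Acot1 at -1.72 and Pdk4 at -1.47. Oxidative phosphorylation genes had a median of -0.39, with 34 of 37 below 0 but 0 past 2-fold, and Sdha lowest at -0.93.

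Cardiomyocyte contractile and marker genes had a median of -0.70, with members that differed in both directions. Of 33 members, 7 were at least 2-fold lower, including the atrial light chains Myl7 at -2.30 and Myl4 at -1.72, the myosin heavy chain Myh6 at -2.11 and the mitochondrial creatine kinase Ckmt2 at -1.74. Another 4 were at least 2-fold higher, including the M-band gene Myom2 at 2.14 and Csrp3 at 1.81. Ion channel and calcium handling genes had a median of -0.25, with Kcnip2 at -1.78 and Hrc at -1.55. These differences accompanied the higher macrophage markers and the lower endothelial markers in the same array.

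The EGFR and c-Met list had a median of -0.01 under fibroblast medium, within the random lists, and its ligands and receptors differed in sign. Tgfa was higher by 1.44 and Hbegf by 1.27, the only members past 2-fold, followed by Areg at 0.99 and Ereg at 0.81. Erbb2 was at -0.85, Egf at -0.58, Egfr at -0.31, Erbb4 at -0.17, Btc at -0.10, Nrg2 at -0.07, Hgfac at -0.06, Erbb3 at -0.02 and Met at 0.06. Hgf and Mst1, which had no value on any array, were read as 0.00. Nrg1 had a mean of 0.30 over probe sets from -0.29 to 1.31. Among MAPK feedback and immediate-early genes, 6 of 28 were at least 2-fold higher, with Ier3 at 1.85, the cyclin gene Ccnd1 at 1.73, Dusp1 at 1.58 and Junb at 1.41 (median 0.26), and Dusp5 was at -0.64 and Egr1 at -0.58. Antioxidant enzyme genes had a median of 0.18, with the superoxide dismutases Sod3 at 2.03 and Sod2 at 1.69 and the glutathione peroxidase Gpx3 at 1.53. Nrf2 targets had a median of 0.42, with Ephx1 at 1.34 and Me1 at 1.21, and Gsta4 at -1.34. Cholesterol synthesis genes had a median of 0.70, with Idi1 at 1.71, and the ATF4 and amino acid response list a median of 0.38, with 5 of 37 at least 2-fold higher, among them Nupr1 (4.01-fold) and Cebpb at 1.79.

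In total, 605 genes were at least 2-fold higher and 369 at least 2-fold lower in fibroblast medium than in control, and 4 of the 234 such genes with several probe sets had a probe set of opposite sign. Of the 37 lists, 24 lay outside the central 95% of random lists, but 14 did so when random lists were drawn only from genes of the fixed lists, a setting chosen after the data were seen. Lists for MAPK feedback, antioxidant enzymes, fibroblast matrix and secreted factors were among those that no longer did. Medians of 8 lists exceeded the largest difference of the added control transcripts, 0.68, 5 of them higher and 3 lower. Those of macrophage, inflammatory, myofibroblast and endothelial genes lay well beyond it. The medians of cholesterol synthesis (0.70), cardiomyocyte (-0.70), hypertrophy (0.72) and fatty acid oxidation genes (-0.76) passed it only by a little. With only probe sets that had values on 2 arrays, the endothelial median was -2.60, the MAPK feedback median 0.68, the interferon-response median -0.38, the ion channel median -0.49 and the secreted factor median 0.45. With the probe set with the widest range, the ion channel median was -0.50, the secreted factor median 0.35 and the fibroblast matrix median 0.33.

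The third comparison set the conditioned media against each other and asks which differences go with the donor cell. Myoblast medium had lower macrophage markers (19 of 22 at least 2-fold lower, median -2.49) and lower inflammatory genes (22 of 35, median -2.09), with Adgre1 at -6.22, Lyz2 at -5.73, Il1b at -5.07, Cxcl1 at -4.89 and Ccl2 at -4.79. Grem1 was lowest at -6.73, and Ch25h (-4.82), Ccl9 (-4.81), Ccn3 (-4.74), Ccl7 (-4.58), Ccl4 (-4.49) and Pilra (-4.37) were also among the 12 lowest. Endothelial markers were higher in myoblast medium, with 9 of 18 past 2-fold and a median of 1.06, led by Emcn at 4.28, and Nos3, the endothelial nitric oxide synthase gene, was higher by 2.79. Sparcl1 (3.97), Dhrs7c (3.36), Hbb (3.32), Col6a6 (3.26), Lyve1 (2.96), the imprinted RNA H19 (2.89), Cyyr1 (2.88) and the keratin gene Krt19 (2.87) were among the highest.

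The ATF4 and chaperone lists also separated the media. Heat shock genes and antioxidant enzymes did not stand apart, with medians of -0.04 and -0.05, and p53 targets were lower in myoblast medium (median -0.19). The ATF4 list was higher in myoblast medium, with 16 of 37 past 2-fold and a median of 0.93, led by Ddit3 at 3.29 and Trib3 at 2.87, and the chaperone list had a median of 0.61 with 8 of 24 past 2-fold. Fatty acid oxidation genes were higher by a median of 0.56, with Acot1 at 2.25 and Plin5 at 2.03, and cardiomyocyte markers by 0.44, with Ckmt2 at 2.20 and Myh6 at 1.94 but Myom2 at -2.91. Nrf2 targets were higher in myoblast medium by a median of 0.28, with Slc7a11 at 2.07 and Nqo1 at 1.30 but Ephx1 at -1.29. Against control, however, their median was larger in fibroblast medium (0.42) than in myoblast medium (0.29). Medians of differences do not add, so the list does not rank the media clearly. MAPK feedback genes had a median of -0.34 (-0.69 with only probe sets that had values on 2 arrays), with Dusp1 at -1.96. Of the EGFR and c-Met list, Hbegf alone passed 2-fold, at -1.04, and the list median was -0.04. Egf was at 0.94, Erbb2 at 0.34, Erbb4 at 0.23, Areg at -0.83, Tgfa at -0.82, Ereg at -0.81, and Egfr at -0.09 and Nrg1 at -0.16, each with probe sets of differing sign. Counts were 302 genes at least 2-fold higher and 560 at least 2-fold lower in myoblast medium, and 25 of 37 lists lay outside the random lists. Of these lists, 3 had medians beyond the largest difference of the added control transcripts, those of endothelial, macrophage and inflammatory genes, but with the median of a gene's probe sets the endothelial median was 0.92, within it.

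The differences of the conditioned media from control were compared across genes, which are not independent replicates. Sox7 (-3.01 and -4.94 in myoblast and fibroblast medium), Sned1 (-2.84 and -3.22) and Col6a6 (-1.97 and -5.22) were lower in both media, and Cth (4.15 and 2.96), Cnn1 (3.02 and 2.69), Nppb (2.02 and 3.70) and Serpinb2 (2.05 and 4.35) were higher in both. At the 2-fold threshold 65 genes were higher in both media and 70 were lower in both, and 14 passed it in opposite directions. Independent lists would share 8.17 and 3.12 genes, and 3 simulated arrays with equal error and no effect shared 2 and 1. Under the simulated normal error, with an SD of 0.235 per array, few genes pass 2-fold at all. Its counts of 2 and 1 are therefore no yardstick for 65 and 70. Pearson's r was 0.366 and Spearman's rho 0.344 over 14217 genes. The simulated arrays gave r of 0.50, because both differences use the same control array. The covariance was 0.0711 against 0.0551 simulated. That simulation assigned the spread between myoblast medium and control to error shared equally by the arrays. If all of that spread lay in the control array, the covariance from it alone would be 0.111, above the observed value, so the covariance does not show a shared effect. With 1 control array the controls could not be split, so part or all of the overlap may come from the control array itself. This holds for the interferon-response genes too. Their median was -0.20 in each medium against control, but -0.05 in myoblast against fibroblast medium.

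**Figure D3:**
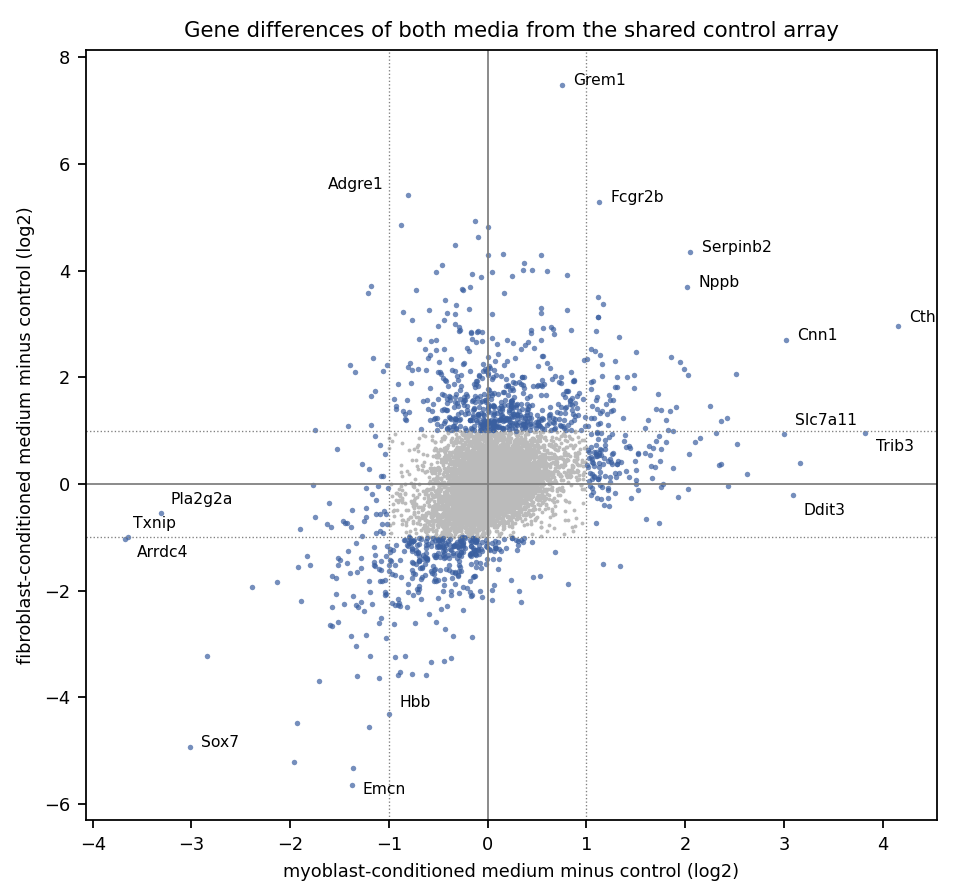
Log2 difference of each gene for myoblast-conditioned medium minus control (horizontal axis) and fibroblast-conditioned medium minus control (vertical axis), 1 array per condition. Blue points passed 2-fold in at least 1 comparison and dotted lines mark 2-fold; Cth and Trib3 lie far to the right, at 4.15 and 3.82, and Grem1 at the top, at 7.48.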

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

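All tests in this part were chosen after the results were seen. Probe sets outside the gene comparisons also differed from control, in both directions. Of 9780 probe sets with no gene name here, Affymetrix controls left out, 57 were at least 2-fold higher and 38 lower in myoblast medium. In fibroblast medium 208 of them were higher and 193 lower. Of 436 with several genes, 4 were higher and 3 lower in myoblast medium, and 11 higher and 13 lower in fibroblast medium. Beside these, 192 and 120 of 14217 genes passed 2-fold in myoblast medium, and 605 and 369 in fibroblast medium. The added poly-A controls were higher in myoblast medium than in control by a median of 0.34, and the hybridisation controls were higher in fibroblast medium by a median of 0.40.

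Macrophage and inflammatory genes were far higher in fibroblast medium than in control. Scaling or labelling that shifts all genes alike is argued against, since the largest difference among the added control transcripts was 0.68 and the macrophage list median was 2.09. Labelling that differs between genes was not tested. A larger share of leukocyte RNA was not tested apart from the markers that form the pattern, and stays open. Whether a larger share of unchanged leukocytes is the whole cause cannot be told apart from a change in their state, because 5 markers, including C1qb at 0.54 and Cd163 at 0.08, named after their values were seen, were under 2-fold and their levels are unknown. The medium itself and a difference between cultures remain open with 1 array per condition.

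Cardiomyocyte and fatty acid oxidation genes were lower in fibroblast medium. A smaller share of cardiomyocyte RNA may account for part or all of the lower values. It would not by itself give the 4 of 33 cardiomyocyte markers that were at least 2-fold higher. Those markers do not show what lowered the others, so this cause stays open. RNA degradation cannot be told apart from the treatment. The 5' minus 3' difference of 3 control genes had a median of -0.22, but ranged from 0.01 for GAPDH to -0.85 for hexokinase. An effect of the medium on the cells was not tested.

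ATF4 target and chaperone genes were higher in myoblast medium. Scaling or labelling that shifts all genes alike is argued against for the ATF4 list. Its median was 1.31, and the largest difference among the added controls was 0.66. The chaperone median of 0.76 lay only a little above that difference. Whether the controls were added in equal amounts is not known, and labelling that differs between genes was not tested. The highest difference among 23 skeletal muscle markers was 0.25, but this cannot exclude RNA carried over from skeletal myoblasts. The markers Myf5, Pax7, Pax3 and Megf10 had no probe set with that symbol alone. Of the 23, 8 had a difference of exactly 0, and their levels are unknown. Depletion of amino acids or glucose from the medium was not tested against secreted factors, and both stay open. The low Txnip and Arrdc4 values, at -3.68 and -3.64 in myoblast medium, were less low in fibroblast medium, where Txnip was at -1.03.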

How the results depend on the processing

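With 1 array per condition no replicate could be left out. No paired analysis was possible because each condition has 1 array and no test was run. Not run, for want of absolute levels, were the floors at the 30th and 70th percentile and repeated quantile normalization. At 1.5-fold, 536 genes were higher and 407 lower in myoblast medium than in control, 1293 and 991 in fibroblast medium, and 946 and 1186 in myoblast against fibroblast medium. At 3-fold these counts were 54 and 21, 262 and 141, and 84 and 255, as the threshold itself sets. Under the other settings that gave gene counts, all 6 counts stayed within 1.5 times the main ones. Of these settings, nonzero genes only could not change a 2-fold count, and centring on nonzero genes left all 6 unchanged. No list that stood apart had the opposite sign, and neither did any of the 12 largest differences per direction and comparison where measured. Other named genes, such as members of the EGFR and c-Met list, were not checked for sign across settings. List medians were less stable. Of 111, 74 differed by more than the spread of random lists with probe sets with 2 values only, 44 with the probe set with the widest range, 24 with nonzero genes only, 8 with the median of a gene's probe sets and 6 without cross-hybridising probe sets. Among the 73 medians that stood apart, 19, 11 and 1 under the first 3 of these were over 1.5 times the main size, while 1 with the widest range, 5 with the median and 3 without cross-hybridising probe sets were under it by as much. With probe sets with 2 values only, the endothelial median in fibroblast medium over control was -2.60 in place of -1.35, the MAPK feedback median 0.68 in place of 0.26, and the interferon-response median in myoblast medium over control -0.67 in place of -0.20; that setting leaves out probe sets with ties at 0. Settings chosen after the data were seen were the probe set with the widest range, probe sets with 2 values only, genes with a nonzero value only, arrays centred on genes with a nonzero value, and random lists drawn from the fixed lists' genes. Under the last, 14 lists stood apart for fibroblast medium over control in place of 24; the cause was not tested. Of the 73 list calls over the 3 comparisons, 49 were kept there and 61 with probe sets with 2 values only; over all 9 settings 15 of 24 held for myoblast medium over control, 14 of 24 for fibroblast medium over control and 19 of 25 between the media. Centring on the median of all genes moved nothing, since every array's median was 0, and so says nothing about stability. The number of arrays limits precision, and signal over background is unknown.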

Other observations

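Lists that the comparisons above left out are given here as values. In myoblast medium against control, S phase and replication genes had a median of -0.10, with Mcm6 at -0.60 and Mcm2 at -0.54, and G2 and M phase genes one of 0.05. In fibroblast medium the same lists had medians of -0.02 and 0.04. Matrix proteases and their inhibitors had a median of -0.22 in myoblast medium, with Plau at -1.08, and 0.15 in fibroblast medium, with Mmp12 at 3.08 and Mmp3 at 2.36. Of 17 p53 target genes, 4 were at least 2-fold higher in myoblast medium and 5 in fibroblast medium, where Cdkn1a was higher by 2.53. The list median was 0.06 in myoblast medium, within the random lists, and 0.30 in fibroblast medium. This list shares Gdf15 with the hypertrophy list and Sesn2 with the ATF4 list. Glucocorticoid-response genes had medians of -0.04 and 0.26, heat shock genes 0.05 and 0.07, and clock genes 0.09 and 0.00 in myoblast and fibroblast medium. Some of these medians depended on the probe sets used. With the probe set with the widest range, that of matrix proteases was -0.34 in myoblast and 0.23 in fibroblast medium and that of clock genes 0.19 in myoblast medium, and with only probe sets that had values on 2 arrays that of S phase genes was -0.23 in myoblast medium.

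Epicardial and mesothelial markers differed in sign within the list. Krt18 was higher in both media, at 1.17 in myoblast and 3.38 in fibroblast medium, while Krt19 was at 1.34 and -1.53. Smooth muscle and pericyte markers had medians of -0.20 (-0.37 with the probe set with the widest range) and 0.07, and Schwann cell and neuron markers 0.00 in both. Of 13 erythroid genes, Hbb alone passed 2-fold, and was lower in both media, at -4.32 in fibroblast medium. Among probe sets with no gene name or several, the lowest difference of fibroblast medium from control, -8.77, belonged to one that the annotation pairs with several genes. Ribosomal protein genes had medians of 0.02 and 0.00 and reference genes medians of 0.00 and -0.04. A control probe set for 5S ribosomal RNA was lower in both media than in control, at -1.08 and -1.31, a gene outside the naming rule that was chosen after its values were seen.

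The poly-A controls, added before labelling, and the hybridisation controls, added after it, differed between the conditioned media in opposite directions. All 24 poly-A control probe sets were higher in myoblast than in fibroblast medium, by a median of 0.58, and all 18 hybridisation control probe sets were lower, by a median of -0.28. No explanation of this was tested.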
